A study of Arabidopsis thaliana with 28 samples.

How the data were processed

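Affymetrix ATH1 arrays were hybridised with biotin-labelled target made from total RNA of leaves of Arabidopsis thaliana Col-0. Of 28 arrays, 27 entered the comparisons. The values deposited by the authors are an intensity per probe set, the linear MAS5 signal per the submitters' processing notes. Each array was found to be scaled to a 2% trimmed mean of 100. No version of MAS5 is given in the sources used here, and detection calls were not used. The array medians ran from 40.8 to 48, the highest signal of an array from 3066 to 6992, and the 100 strongest probe sets held 7.73% to 13.7% of the summed signal.

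The table holds 22810 probe sets, of which 64 are controls. The gene table lists 14016 of them, 13513 with 1 gene and 503 with several, and 8730 are not listed, so their genes are not named here. Of the names used, 13436 were matched by gene identifier in the annotation of assembly TAIR10.1, from which names, locus codes and chromosomes were taken. Of the probe sets tested, 7434 had 1 gene and 6213 had no name.

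Samples were grouped by the labels into developing leaves at 2, 4, 12, 24, 48 and 96 h with 4 replicates each and mature leaves at 24 h with 2. The arrays both titled 24 h replicate 1 were averaged on the log2 scale and counted as 1 replicate, leaving 26 replicates. One array is titled 4 h replicate 1, as is another, but its treatment note gives 4 h ES where those of the other developing arrays give AS, and since these letters are undefined it was assigned to no group.

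Signals were transformed as log2 after adding 10. Probe sets whose mean lay above the 40th percentile, equal to a signal of 27.8, were tested, which left 13647. All 7 groups were fitted in 1 linear model with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), with 19 residual degrees of freedom. The comparisons were 4, 12 and 24 h against 2 h, 48 and 96 h against 24 h, mature against developing leaves at 24 h, and a moderated F test over the 6 times. The tests are two-sided. Adjusted p-values follow Benjamini and Hochberg over the probe sets tested, with a threshold of 0.05. On simulated data the steps recovered 58.2% of changes of 0.5 on the log2 scale, 94% of 1 and 100% of 2 in the comparison of 12 h with 2 h, with 8 false among 176 calls, and 35.8%, 88.1% and 100% in the comparison of leaf ages, with 10 false among 159. The simulated noise was independent between probe sets, and far fewer probe sets changed than were called in the data. These rates therefore need not hold for the data.

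The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names the 10 largest rises and 10 largest falls among probe sets past the threshold with 1 named gene, no overlap between the values of both groups, and a mean in the higher group above 44.1, the median of all probe sets. It takes the 4 largest of each for 4 h against 2 h and 48 h against 24 h, and up to 4 members of each gene list. For each gene the probe set with the highest mean was used. The plots by time show 6 genes picked from these after their values were seen.

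There were 23 lists with 369 members, of which 47 had a named probe set and 38 were tested. The 8 lists with at least 3 tested members (light harvesting, photosystem subunits, Calvin cycle, photorespiration, sugar starvation, flavonoid, stomatal development and cell cycle) were tested in the 6 contrasts with camera at a preset correlation of 0.01, adjusted over 48 tests. The minimum of 3 was set after seeing the data. Another 7 lists had 1 or 2 tested members, which were tested only as single genes, and 8 had none, among them the markers of meristem, flower and epidermis, so signal from these tissues was not examined.

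The alternatives were pseudocounts of 1 and 50, no filter or a filter at the 60th percentile, quantile normalization, median centring, a replicate block, only the compared groups in the fit, array quality weights, eBayes without trend, other uses of the doubled 24 h arrays, developing replicates 1 and 2 only against mature leaves, a minimum change of 2-fold, an estimated correlation in camera, and each replicate left out in turn. An alternative without replicate 1 of any group, and families of genes that share a symbol stem or lie on the plastid chromosome, were chosen after seeing the data. Permutation tests are exact for groups of 4 and use 100000 draws for the correlation over 24 replicates.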

Results

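Transcript levels were measured on Affymetrix ATH1 arrays in leaves of Arabidopsis Col-0 plants given low light at ambient CO2 in a growth room with a 10 h light period. Developing leaves, at insertions 19 to 21, were sampled after 2, 4, 12, 24, 48 and 96 h of treatment with 4 replicates at each time, and mature leaves after 24 h with 2 replicates. The series title places these samples in a study of how signals about irradiance and CO2 pass between leaves. No untreated or high-light array is used here, so each comparison is between times or leaf ages and gives no effect of low light itself. The clock time of sampling is not given in the sources used here, and neither is the meaning of the letters AS and ES in the treatment notes. It is therefore not established whether the sampled leaves were themselves in low light, or whether mature and developing leaves were treated alike. The median signal of an array was 44.1, 41.1, 43.9 and 43.1 for replicates 1 to 4 at 2 h, 42.6, 44.9, 41.8 and 45 at 4 h, and 45.1, 42.9, 43.3 and 44.5 at 12 h. It was 46.5, 42, 42.9 and 45.6 at 24 h, with 44.8 on the second array titled replicate 1, then 48, 42.4, 43.7 and 44.1 at 48 h, and 45.6, 43.5, 43.7 and 45.6 at 96 h. The mature arrays had medians of 43.2 and 40.8. The number of arrays limits the precision. Levels below are means of the MAS5 signal ± SD, with n = 4 for each developing group and n = 2 for mature leaves, and log2 changes are given ± SE. The log2 changes and folds are of the signal plus 10, so they are smaller than the ratio of the mean signals where a group is near background. For genes with a group mean under 27.8 no fold is given, and the size of a log2 change there depends on the added 10. The labels do not say whether replicates are separate plants or cultures, so the p-values measure only the spread between these samples.

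Across the 6 times in developing leaves, GI (GIGANTEA, a component of the circadian clock with an evening phase) went from 69.3 ± 6 at 2 h to 176 ± 8.32 at 4 h and 11.3 ± 2.61 at 12 h, then stood at 50.7 ± 10.5 at 24 h, 46.5 ± 4.45 at 48 h and 53.5 ± 8.02 at 96 h. AT3G09440, a chaperone gene of the HSP70 family, stood at 490 ± 22.4 at 2 h, 152 ± 10.2 at 12 h, 2410 ± 259 at 24 h, 2430 ± 264 at 48 h and 2440 ± 178 at 96 h. The moderated F test of limma over the 6 times passed for 7872 of 13647 probe sets tested, or 57.7%. Of these, 2848 had their highest mean at 12 h, 1738 at 96 h, 1144 at 4 h, 930 at 2 h, 652 at 24 h and 560 at 48 h.

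**Figure D1:**
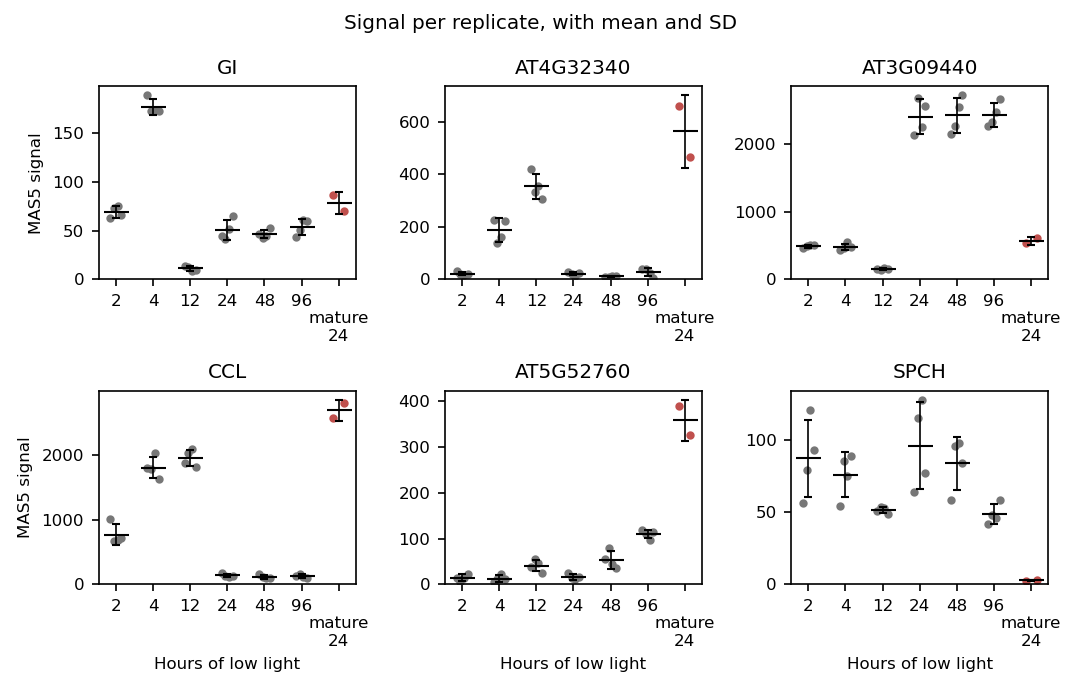
MAS5 signal of 6 genes against hours of treatment in developing leaves (grey points, 4 replicates) and in mature leaves at 24 h (red points, 2 replicates), with the mean and SD as bars. The axis names these as hours of low light, but they include nights. Whether the sampled leaves were themselves in low light is not established. GI peaked at 4 h with a mean of 176, CCL was 137 in developing and 2690 in mature leaves at 24 h, and SPCH was 96 and 2.71.

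The first comparison asks what changed between 2 h and 4 h of treatment in developing leaves. AT4G32340 rose from 22.6 ± 6.02 to 188 ± 44.9 (log2 change 2.59 ± 0.24, adjusted p = 4.2e-08), and AT1G56300 rose 6-fold, from 57.5 ± 12.5 to 392 ± 47.5 (2.59 ± 0.16, adjusted p = 2.9e-11). PDC2, a pyruvate decarboxylase gene, rose 2.94-fold to 149 ± 24.5, and AT4G16146 rose 3.33-fold to 154 ± 22.2. The falls were smaller. AT1G65490 fell from 344 ± 136 to 149 ± 16.7, and AT5G15950, which encodes an S-adenosylmethionine decarboxylase, fell from 174 ± 40.2 to 82.9 ± 10.8. AT5G64850 fell from 191 ± 23.8 to 93.3 ± 15.9. AT5G62210 fell from 396 ± 72 to 208 ± 76.2 (adjusted p = 0.012), a call that ended without 4 h replicate 1 (adjusted p = 0.065), 4 h replicate 3 (0.062) or 2 h replicate 4 (0.061).

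Of the gene lists, the flavonoid list had 4 tested members, with a median log2 change of -0.55 at 4 h against 2 h (camera, adjusted p = 0.0051, and adjusted p = 0.38 with an estimated correlation). Over all probe sets 1 member fell, CHIL (chalcone isomerase-like), and 4 fell adjusted over the list alone. The list lost its call without 2 h replicate 2 (adjusted p = 0.07) or 4 h replicate 3 (0.064), and over its 41 alternatives the adjusted p ran from 0.00086 to 0.38. CHIL fell from 197 ± 31.8 to 121 ± 26.3 (adjusted p = 0.029), and lost its call without 2 h replicate 2 (0.079), 2 h replicate 3 (0.11), 2 h replicate 4 (0.069), 4 h replicate 3 (0.15) or 4 h replicate 4 (0.059), with a pseudocount of 1 (0.14) or with no filter (0.061). GI rose by a log2 change of 1.24 ± 0.12 (adjusted p = 1.4e-07). Both tested genes of starch breakdown rose, DPE1 (disproportionating enzyme) from 123 ± 14.8 to 218 ± 13.6 and PWD (phosphoglucan water dikinase) to 271 ± 35.3 (log2 change 0.7 ± 0.095). In the light-harvesting list LHCB4.3 fell by 0.51 on the log2 scale (adjusted p = 0.026), without a call when 2 h replicate 1 (0.11), 4 h replicate 3 (0.13) or 4 h replicate 4 (0.1) was left out or only the compared groups were fitted (0.11). None of the 4 photosystem, 4 Calvin cycle, 3 photorespiration, 3 sugar starvation, 3 stomatal or 3 cell cycle members passed by limma over all probe sets, where 1788 of the probe sets tested had an unadjusted p under 0.05. Adjusted over the list alone, 2 cell cycle members rose and 1 fell. In total 379 probe sets changed, 218 up and 161 down, and 46 of them changed at least 2-fold, 35 up and 11 down.

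The second comparison sets 12 h against 2 h. AT4G32340 rose to 354 ± 48.4 (log2 change 3.49 ± 0.24, adjusted p = 5.2e-12), AT3G60420 rose from 24.9 ± 15.4 to 275 ± 45.7, and AT1G26665 rose 5.13-fold to 325 ± 40. AT3G16530, of the legume lectin family, rose from 43 ± 21.8 to 251 ± 93.7, and the cyclophilin gene AT2G21130 rose from 54.1 ± 6.53 to 269 ± 33.3. SCPL49, a serine carboxypeptidase-like gene, rose from 185 ± 9.49 to 823 ± 46.4. AT3G21670, a gene of the nitrate transporter family NPF, fell from 370 ± 13.5 to 31.7 ± 11 (log2 change -3.23 ± 0.13, adjusted p = 4.2e-17). AT1G13650 fell from 141 ± 35.9 to 6.16 ± 5.34, and the cytochrome P450 gene CYP71B26 fell from 232 ± 24.9 to 24.6 ± 8.86. The other genes named for their size, AT1G56300, AT3G59350, AT3G62550 and AT1G78020 among the rises and AT5G62210, AT5G12110, AT3G01060, AT3G28220, AT5G48490, AT5G35970 and AT1G76240 among the falls, changed by log2 values of 2.01 to 2.18 and -2.59 to -2.1.

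In the sugar starvation list 2 of 3 members rose, over all probe sets and adjusted over the list alone. AKINBETA1, a beta subunit of the SnRK1 kinase, went from 166 ± 28.3 to 484 ± 114 and MCCA, a subunit of methylcrotonyl-CoA carboxylase in leucine breakdown, from 56.9 ± 4.37 to 138 ± 35.8. IVD had a log2 change of 0.26 (adjusted p = 0.28). The list as a whole had a median of 1.11 and did not pass (camera, adjusted p = 0.098), except with no filter (0.023, in a range of 0.023 to 0.38 over 41 alternatives). Both genes of starch breakdown rose, PWD by 1.47 ± 0.095 and DPE1 by 1.01 ± 0.12. Both genes of starch synthesis fell, SBE2.2 from 227 ± 23 to 162 ± 8.56 (adjusted p = 0.019, and 0.064 without 2 h replicate 2) and APL3 from 46.4 ± 5.24 to 31.8 ± 5.37 (0.036). APL3 lost its call without 2 h replicate 3 (0.098), 2 h replicate 4 (0.076), 12 h replicate 2 (0.13) or 12 h replicate 3 (0.065), with a pseudocount of 50 (0.059) or with no filter (0.068). In the photosystem list 3 of 4 members fell, PSAN by a log2 change of -0.67 ± 0.12, again 3 adjusted over the list alone, with a list median of -0.52 and adjusted p = 0.15 (0.045 with no filter). The light-harvesting genes went both ways. LHCB4.2 fell from 2420 ± 433 to 687 ± 55.9, LHCB4.3 rose from 383 ± 56 to 669 ± 66.6, and LHCB4.1 had a log2 change of -0.28 (adjusted p = 0.097). Adjusted over the list alone, 1 of these 3 rose and 2 fell (list median -0.28, adjusted p = 0.59). GI fell by 1.9 on the log2 scale. PRL, which encodes the replication factor MCM7, fell from 270 ± 55.9 to 114 ± 11.1, and AUR1, an Aurora kinase gene, rose by 0.37 ± 0.12 (adjusted p = 0.013), a call that ended without 2 h replicate 1 (0.06) or 12 h replicate 2 (0.052). AUR2 had a log2 change of 0.29 (adjusted p = 0.15). The cell cycle count was 1 up and 1 down of 3, also adjusted over the list alone (list median 0.29, mean -0.16, adjusted p = 0.93).

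Of the 3 stomatal genes, STOMAGEN (EPFL9, a secreted peptide that promotes stomata) rose by 0.42 ± 0.11. SPCH (SPEECHLESS, a transcription factor that starts the stomatal lineage) fell by 0.62 on the log2 scale (adjusted p = 0.011), a call that ended without 2 h replicate 3 (0.063). WRKY53, of the senescence list, rose by 0.71 ± 0.15. In the flavonoid list 3 of 4 members fell, and 4 adjusted over the list alone (list median -0.57, adjusted p = 0.17). CHIL fell by 0.73 on the log2 scale. Without 12 h replicate 1 the calls of both DFR (adjusted p = 0.062) and UGT78D2 (0.096) ended, leaving 1. DFR also lost its call without 2 h replicate 2 (0.092), 2 h replicate 4 (0.093) or 12 h replicate 4 (0.073) or with no filter (0.055), and UGT78D2 without 2 h replicate 3 (0.056) or 12 h replicate 3 (0.052). In total 5287 probe sets changed, 2779 up and 2508 down (2619 and 2650 with quantile normalization, 2464 and 2826 with median centring), with 672 changed at least 2-fold, 285 up and 387 down. The actin 3' to 5' log2 ratio, a measure of RNA or target quality, was 1.76 ± 0.35 at 12 h and 2.56 ± 0.51 at 2 h (two-sided exact permutation p = 0.057, adjusted p = 0.77 over 18 tests). With groups of 4, a single difference cannot pass this test after adjustment over 18 tests, so equal quality is not shown.

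**Figure D2:**
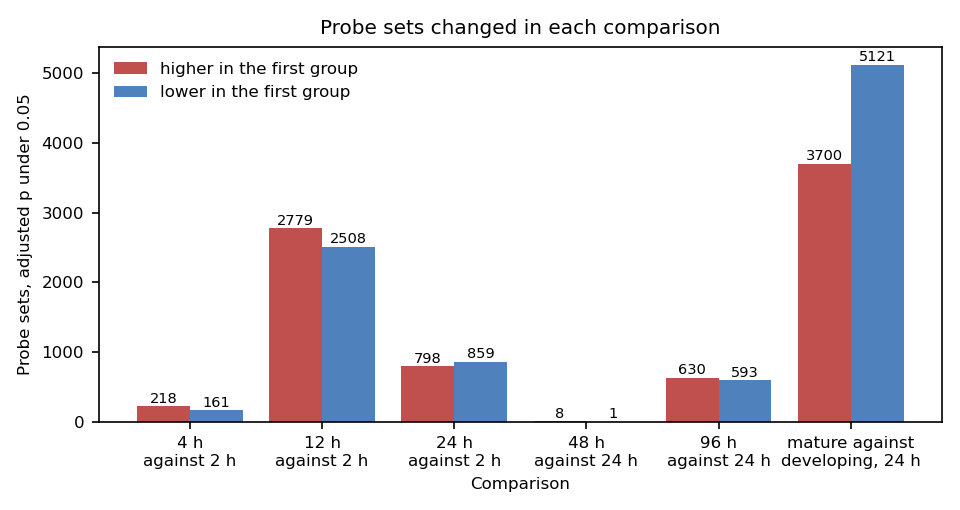
Number of probe sets with an adjusted p under 0.05 in each of 6 comparisons, higher (red) or lower (blue) in the first group named. The counts ran from 8 and 1 for 48 h against 24 h to 3700 and 5121 for mature against developing leaves.

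The third comparison sets 24 h against 2 h, a day after the start. AT5G48570, a peptidyl-prolyl isomerase gene of the FKBP family, rose 6.15-fold from 33 ± 8.4 to 259 ± 81.7 (log2 change 2.62 ± 0.2, adjusted p = 2e-10), AT3G09440 rose 4.82-fold (2.27 ± 0.094, adjusted p = 1.4e-15), and Hsp70-2 rose from 79.9 ± 13.1 to 255 ± 14.9. HYH, a bZIP transcription factor gene related to HY5 that acts in light responses, rose from 28.4 ± 8.16 to 104 ± 4.67, and MGL, methionine gamma-lyase, rose from 43.8 ± 12.2 to 165 ± 47.8. AT1G06000, a flavonol rhamnosyltransferase gene, rose from 328 ± 31.5 to 902 ± 109. CCL fell from 770 ± 163 to 137 ± 25.4 (log2 change -2.4 ± 0.15, adjusted p = 9.3e-12), AT2G30600 from 262 ± 42.9 to 51.6 ± 10.6, AT3G15630 from 217 ± 54.2 to 40.7 ± 4.81 and AT3G15450 from 1150 ± 253 to 272 ± 28.9. Among the other genes named for their size, AT5G12110, AT3G14200, AT3G07090 and AT2G20560 rose by log2 values of 1.41 to 2.18, and AT1G70820, AT4G34950, AT2G39920, AT2G39400, AT3G51660 and AT1G56220 had changes of -1.87 to -1.48.

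In the sugar starvation list 2 of 3 members fell, over all probe sets and adjusted over the list alone, MCCA from 56.9 ± 4.37 to 29.3 ± 4.26 and AKINBETA1 from 166 ± 28.3 to 102 ± 27.6 (list median -0.67, adjusted p = 0.098, and 0.023 with no filter). DPE1 fell from 123 ± 14.8 to 66.5 ± 12.2, and PWD stood at 163 ± 18.5 (adjusted p = 0.99). In the flavonoid list CHIL rose from 197 ± 31.8 to 340 ± 57.1, and the count was 2 up of 4, also 2 adjusted over the list alone (list median 0.34, adjusted p = 0.17). The other riser, UGT78D2, went from 166 ± 11.5 to 246 ± 36.6 (adjusted p = 0.04) and lost its call with no filter (0.075) or without 2 h replicate 1 (0.09), 2 (0.08), 3 (0.054) or 4 (0.071) or 24 h replicate 2 (0.14), 3 (0.065) or 4 (0.069). In the Calvin cycle list 2 of 4 members rose, and 3 adjusted over the list alone (list median 0.35, adjusted p = 0.17), and without 24 h replicate 1 both calls ended. One was RCA (Rubisco activase), from 2860 ± 440 to 4020 ± 685 (adjusted p = 0.014), without a call when 24 h replicate 1 (0.074) or 2 h replicate 3 (0.073) was left out or only the compared groups were fitted (0.054). The other was SBPASE (sedoheptulose bisphosphatase), from 1730 ± 173 to 2220 ± 355 (adjusted p = 0.041). It lost its call in 12 of 22 alternatives (adjusted p from 0.013 to 0.18 over all 22), among them quantile normalization (0.095) and leaving out 24 h replicate 1 (0.18), 2 (0.086) or 4 (0.057) or 2 h replicate 2 (0.06), 3 (0.15) or 4 (0.068). The photorespiration gene HPR (hydroxypyruvate reductase) rose from 1380 ± 165 to 2090 ± 588, the only one of 3 members to pass over all probe sets or adjusted over the list alone (list median 0.07, adjusted p = 0.37), with adjusted p = 0.052 when only the compared groups were fitted. In total 1657 probe sets changed, 798 up and 859 down, with 136 changed at least 2-fold, 67 up and 69 down. The actin 3' to 5' log2 ratio was 1.85 ± 0.2 at 24 h and 2.56 ± 0.51 at 2 h (two-sided exact permutation p = 0.086, adjusted p = 0.77 over 18 tests). Here too the groups are too small for a single difference to pass after adjustment. Of the arrays both titled 24 h replicate 1, only the first entered this ratio, with 1.64, and the second had 1.78.

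The fourth comparison sets 48 h against 24 h, a whole day apart. AT5G52760 rose from 16.1 ± 6.61 to 53.4 ± 19.2 (log2 change 1.27 ± 0.24, adjusted p = 0.024) and AT4G03450 from 30.2 ± 4.79 to 53.9 ± 12.1 (0.66 ± 0.13, adjusted p = 0.041). Of 13647 probe sets tested, 9 changed, 8 up and 1 down, and 716 had an unadjusted p under 0.05. The count fell to 0 by limma without 48 h replicate 2 (648 at an unadjusted p under 0.05), 24 h replicate 3 (632) or 24 h replicate 4 (601), and was 14 without 24 h replicate 1, 4 without 48 h replicate 1, 3 without 24 h replicate 2 and 17 without 48 h replicate 3. AT5G52760 lost its call without 48 h replicate 1 (adjusted p = 0.1), 48 h replicate 2 (0.2), 24 h replicate 2 (0.12), 24 h replicate 3 (0.14) or 24 h replicate 4 (0.085), and AT4G03450 without the same arrays (0.15, 0.26, 0.2, 0.16 and 0.13) or 48 h replicate 4 (0.1). They also lost it with a pseudocount of 1 (0.11 and 0.054), no filter (0.058 and 0.076), both 24 h replicate 1 arrays as separate samples (0.06 and 0.06) or only the compared groups (0.065 and 0.33). AT5G52760 lost it with the first 24 h replicate 1 array only (0.12), and AT4G03450 with the second only (0.052), a pseudocount of 50 (0.059) or replicate 1 left out of all groups (0.095). Calls ended in 10 and 13 of 21 alternatives, with adjusted p from 0.0049 to 0.2 and from 0.009 to 0.33. No member of the 8 tested lists passed over all probe sets or adjusted over the list alone. GI stood at 46.5 ± 4.45 and RCA at 3570 ± 663.

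The fifth comparison sets 96 h against 24 h. AT3G60420 rose from 26.9 ± 10.1 to 224 ± 34.9 (log2 change 2.69 ± 0.41, adjusted p = 9.8e-05), AT5G52760 rose to 110 ± 9.28 (2.23 ± 0.24, adjusted p = 8.6e-07), and RING1, a RING finger ubiquitin ligase gene, rose 4.61-fold from 65.7 ± 20.4 to 336 ± 68.5. CHI (AT2G43570), a putative chitinase gene, rose from 31.3 ± 4.3 to 152 ± 27, and the lectin family gene AT3G16530 rose from 62.7 ± 22.6 to 264 ± 67.6. AT5G12940, AT5G24210, AT2G18690, AT1G73600 and CYP71B23 rose by log2 values of 1.55 to 1.89. AT4G17470 fell from 208 ± 170 to 15.2 ± 10.7, and AT2G33850 fell from 1390 ± 171 to 696 ± 112. AT3G11600, AT1G54050, AT1G22890, GLC, AT1G66760 and AT2G38870 had log2 changes of -1.03 to -0.91. AT1G62500 had a log2 change of -1.07 (adjusted p = 0.014), which did not pass without 24 h replicate 3 (0.083). AT5G42330 had one of -1.04 (adjusted p = 0.032), which did not pass without 24 h replicate 1 (0.054), 24 h replicate 2 (0.08), 24 h replicate 4 (0.082), 96 h replicate 2 (0.12), 96 h replicate 3 (0.059) or 96 h replicate 4 (0.054), or with no filter (0.065).

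Among list members, EXPA8, an expansin gene, rose from 76.7 ± 15.6 to 153 ± 9.47, and WRKY53 from 22.4 ± 3.89 to 40.1 ± 8.26. SPCH fell from 96 ± 30.3 to 48.5 ± 6.97 (adjusted p = 0.0061), the only one of 3 stomatal genes to pass over all probe sets or adjusted over the list alone (list median -0.21, adjusted p = 0.17). DPE1 fell from 66.5 ± 12.2 to 39.7 ± 6.95. SBE2.2 rose from 168 ± 37.2 to 250 ± 28.5 (adjusted p = 0.02), without a call when 24 h replicate 1 (0.081), 96 h replicate 1 (0.066) or 96 h replicate 4 (0.057) was left out. The 3 sugar starvation members had log2 changes of -0.24, -0.22 and -0.03 and no call. In the cell cycle list none passed over all probe sets by limma and 1 fell adjusted over the list alone (list median -0.34, adjusted p = 0.17). In total 1223 probe sets changed, 630 up and 593 down (955 and 1000 with array quality weights), with 115 changed at least 2-fold, 96 up and 19 down, and 3078 at an unadjusted p under 0.05. The count was 733 without 24 h replicate 3 and 1955 with array quality weights.

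The sixth comparison sets mature against developing leaves, both at 24 h. AT2G33850 was lower in mature leaves, at 7.3 ± 5.3 against 1390 ± 171 (log2 change -6.37 ± 0.16, adjusted p = 2.1e-21), and AT4G29030 was lower at 10 ± 5.65 against 848 ± 285. AT5G45670, of the GDSL lipase family, was lower at 5.13 ± 0.699 against 507 ± 101. AT2G32150 was higher, at 872 ± 11.9 against 15.6 ± 13.9 (5.27 ± 0.38, adjusted p = 2.5e-12), and AT3G62550 was higher at 1010 ± 71.2 against 19.9 ± 0.609. STZ (ZAT10, a zinc finger transcription factor of stress responses) stood at 844 ± 57 against 26.9 ± 7.63, ORA47, an AP2/ERF transcription factor gene, at 931 ± 194 against 31.4 ± 8.06, and CHI at 784 ± 25.8 against 31.3 ± 4.3. AT1G64370, AT2G05540, AT1G67865, AT5G24210 and AT1G67860 were higher by log2 values of 4.31 to 4.58, and AT5G62210, AT1G62500, LCR69, AT4G38660, AT3G54400 and AT1G06000 were lower, with values of -4.73 to -3.96.

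All 3 cell cycle genes were lower in mature leaves, PRL at 38.8 ± 6.35 against 238 ± 24.5, and AUR2 and AUR1, which encode Aurora kinases, at 16 ± 2.75 against 78.6 ± 13 and 45.7 ± 9.52 against 136 ± 18. The count adjusted over the list alone was also 3, and the list median of -1.76 did not pass (camera, adjusted p = 0.098, and 0.023 with no filter). Of the stomatal genes SPCH stood at 2.71 ± 0.589 against 96 ± 30.3 and STOMAGEN at 37.3 ± 9.81 against 310 ± 36.7, while FMA (FAMA) had a log2 change of -0.26 (adjusted p = 0.23). Adjusted over the list alone 2 were lower (list median -2.77, adjusted p = 0.17, and 0.045 with no filter). In the flavonoid list 3 of 4 were lower and 4 adjusted over the list alone, with CHIL at 12.3 ± 11.2 against 340 ± 57.1 and UGT78D2 at 75.7 ± 0.921 against 246 ± 36.6 (list median -1.16, adjusted p = 0.17). All 3 sugar starvation genes were higher, AKINBETA1 at 414 ± 46.4 against 102 ± 27.6, MCCA at 132 ± 0.934 against 29.3 ± 4.26, and IVD (isovaleryl-CoA dehydrogenase, also of leucine breakdown) at 150 ± 15.1 against 36.4 ± 6.44. All 3 passed adjusted over the list alone too, and the list median of 1.85 did not pass (adjusted p = 0.098, and 0.023 with no filter).

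WRKY53 stood at 189 ± 37.9 against 22.4 ± 3.89, WRKY22 of the same senescence list at 61.3 ± 13.7 against 29.9 ± 3.92 and EXPA8 at 765 ± 81.5 against 76.7 ± 15.6. The shade avoidance genes IAA29 and HAT2 stood at 190 ± 24.9 and 242 ± 58.9 against 27 ± 8.7 and 63.6 ± 8.7. Both tested genes of starch synthesis were higher, the branching enzyme gene SBE2.2 at 314 ± 10.4 against 168 ± 37.2 (adjusted p = 0.00018) and APL3, a subunit of ADP-glucose pyrophosphorylase, at 78.6 ± 24.1 against 45.1 ± 7.35 (0.0052). APL3 lost its call without mature replicate 2 (0.2) or with developing replicates 1 and 2 only (0.055). The 4 photosystem genes were higher, over all probe sets and adjusted over the list alone, with PSBY at 4420 ± 615 against 2820 ± 401 (list median 0.53, adjusted p = 0.25). With developing replicates 1 and 2 only, 3 of these 4 calls ended, PSAE-1 (adjusted p = 0.47), PSBW (0.18) and PSAN (0.052). PSAE-1 also did not pass without 24 h replicate 3 (0.092), 24 h replicate 4 (0.094) or mature replicate 2 (0.27), or with no filter (0.056), quantile normalization (0.17), both 24 h replicate 1 arrays as separate samples (0.069) or only the compared groups (0.064). PSBW did not with both arrays as separate samples (0.093) or only the compared groups (0.068), nor without 24 h replicate 2 (0.065), 24 h replicate 3 (0.07), mature replicate 1 (0.05) or mature replicate 2 (0.14). In the light-harvesting list 1 of 3 members was higher and 1 lower (list median 0.27, camera, adjusted p = 0.92). Of 4 Calvin cycle members 1 was higher (list median 0.08, adjusted p = 0.85). Of 3 photorespiration members 2 were higher, and 1 was lower adjusted over the list alone (list median 0.36, adjusted p = 0.62). By limma 8821 probe sets changed, 3700 higher and 5121 lower in mature leaves, with 3822 changed at least 2-fold, 1552 higher and 2270 lower. The median log2 change of all probe sets was -0.10, and quantile normalization brought it to -0.08.

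**Figure D3:**
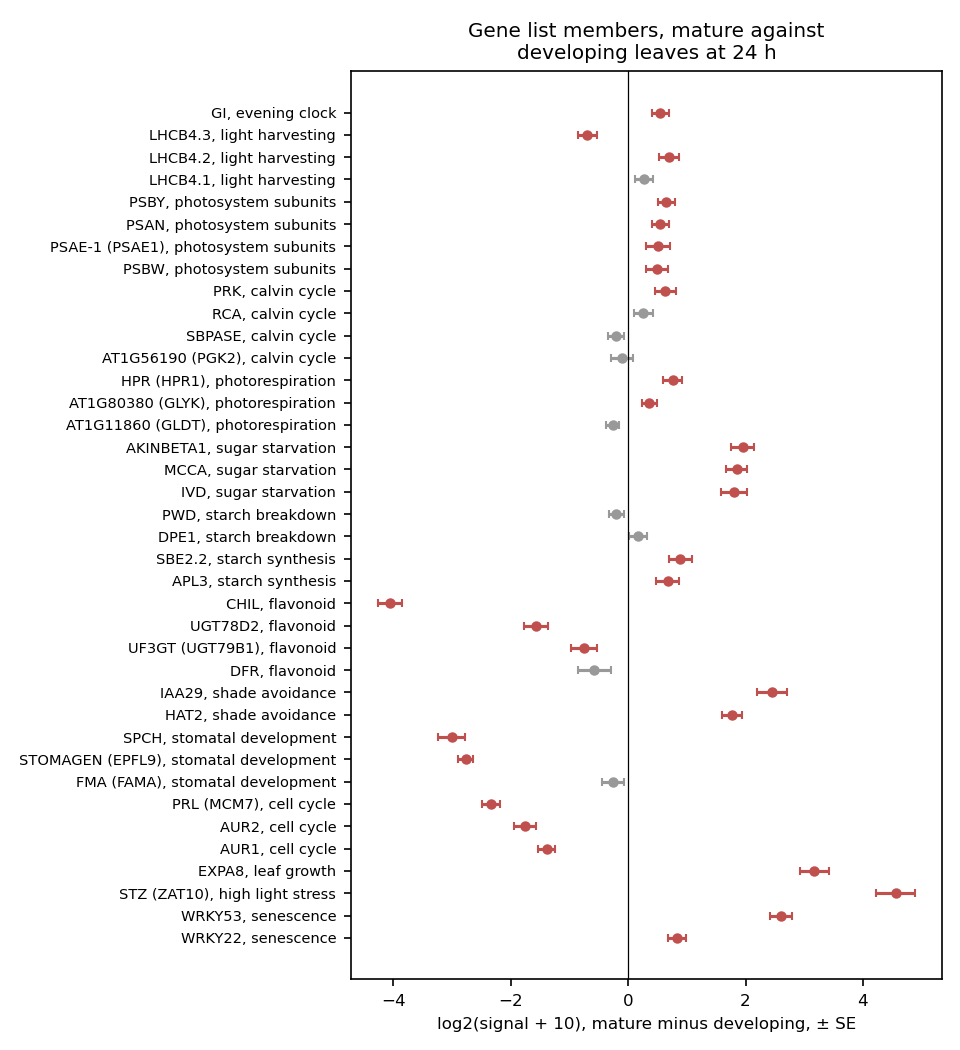
Log2 difference between mature (2 replicates) and developing leaves (4 replicates) at 24 h for tested members of the gene lists, with SE as bars, red for an adjusted p under 0.05 and grey otherwise. The differences ran from -4.06 for CHIL to 4.56 for STZ.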

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

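Of the tests in this part, those on other splits of the samples were planned, while the tests of accumulation, time of day, RNA quality, scaling, leaf ageing, mature tissue and the timing of the mature samples were chosen only after the result was seen, and so were their limits.

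Single values far from the other 3 replicates were found in 6 of 150 gene groups and 3 of 36 array measures, where chance gives about 1 in 20. PDC2 was 39.5 in 2 h replicate 1, with the others at 44.7 to 45.5. SCPL49 was 199 in 2 h replicate 2, with the others at 179 to 181. CCL was 1010 in 2 h replicate 1, with the others at 667 to 712. AT3G60420 was 172 in 96 h replicate 3, with the others at 235 to 250. AT5G12940 was 87.4 in 96 h replicate 2, with the others at 67 to 67.6. AT2G18690 was 27.8 in 24 h replicate 2, with the others at 18.1 to 19.4. The GAPDH 3' to 5' log2 ratio was 0.82 on the first array of 24 h replicate 1 (others 0.2 to 0.27). It was 1 in 48 h replicate 1 (others 0.06 to 0.21) and 0.78 in 96 h replicate 3 (others 0.05 to 0.15). The second array titled 24 h replicate 1, left out of these array measures, had 1.23.

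Splitting the 8 replicates of a comparison in all 35 ways, only the real split (1 of 35) reached its count: 379 for 4 h against 2 h (highest other 11), 5287 for 12 h against 2 h (623), 1657 for 24 h against 2 h (108), 9 for 48 h against 24 h (8) and 1223 for 96 h against 24 h (11). Over the 6 times, 1 of 100 splits reached 7872, the real one, and the highest other gave 1051. For the other counts the real split lay far above the rest, which argues against a random assignment of samples to times. Chance is not excluded, since with 35 splits the share cannot go below 1 of 35 and replicates are taken as exchangeable. The other splits also mix the times, which widens their spread and so the gap. For 48 h against 24 h a gap of 1 probe set lies within the 0 to 17 that leaving out 1 replicate gives and settles nothing. The 2 mature replicates are too few for such splits.

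The first pattern is the large difference between 12 h and 2 h. A change that builds up with time in low light is argued against, since in the genes changed at least 2-fold the 24 h change was -0.04 of the 12 h change (median of 12 choices of separate replicates, -0.12 to 0.09). The choice of scaling and RNA quality as the whole cause are argued against. With quantile normalization 93.4% of the calls stayed, and 78.8% with the actin ratio as a covariate. Both scalings hold the overall signal of arrays alike, so a difference in total signal was not tested. Time of day may account for it: times a whole number of days apart gave 23.1% (96 h against 24 h) and 0.17% (48 h against 24 h) as many calls. A passing response to low light stays open, since no clock times or untreated samples are used here. The light period was 10 h. If the 2 h samples were taken in the light, the 12 h samples fell at its end or in the dark. Light against dark then cannot be told apart from the other explanations.

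The second pattern is the difference between 96 h and 24 h. The choice of scaling is argued against, with 94.9% of the calls kept under quantile normalization. That method too holds the overall signal of arrays alike. Of 71 probe sets changed between 96 h and 48 h, 95.8% differed the same way between mature and developing leaves, which is in line with leaf ageing, though 67.5% of all probe sets tested did so too, and that share, not the limit set, is the fair comparison. Mature tissue in the 96 h samples was first tested by asking how many of 40 strongly mature-biased probe sets had an upper bound under their median implied share of 1.95%, which 5 did (12.5%), against a limit of 5%. After that was seen another form with other limits was put in its place, in which 32 of 40 (80%) lay under the 29.4% that 484 rises would need; this argues against such tissue as the whole cause, but choosing called rises inflates the share needed, and a small admixture stays open.

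The third pattern is the difference between mature and developing leaves at 24 h, whose leaf age, the difference the design names, stays open and untested. Whether both leaf ages were treated alike is not established either. The choice of scaling is argued against, with 97% of the calls kept under quantile normalization and 95% with median centring. The latter gave 4071 higher and 4682 lower in mature leaves. All of these scalings hold the overall signal of arrays alike, so a difference in total signal was not tested. Sampling at another of the times of day covered here is argued against as the whole cause. In 54.7% of 3822 probe sets changed at least 2-fold the mature mean lay over 2-fold outside the range of the 6 developing means. These times cover only part of the day, so a time between them stays open. For genes that vary within the day, sampling time cannot be told apart from age. Mature leaves differed in the 4 h direction for 55.7% of 483 probe sets, in the 2 h direction for 68.3% of 164 and in the 12 h direction for 63.5% of 975, and no clock time decides it.

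At 5 of the 6 times replicate 1 lay farthest to the same side of its group along an axis with 20.6% of the variance within groups, at 17.5 for 2 h, 6.1 for 4 h, 8.5 for 12 h and 24.7 for both 24 h and 48 h. At 96 h it did not (0.7, with replicates 2 and 3 at 1.2 and 1.1). This was tested before the third pattern was chosen in its place for weighing, and no biological explanation was tested. Over 24 replicates the deviation correlated with that of the GAPDH ratio (Pearson r = 0.81, permutation p = 1e-04, Spearman rho = 0.65, permutation p = 0.003). Without the 2 farthest, r was 0.68. The permutations shuffled replicates within each time as if they were independent. Deviations of replicate 1 arrays correlated across times by -0.03 to 0.62, so these p-values may be too small. Among the 18 replicates numbered 2 to 4, r was 0.43 and rho 0.26, a condition added to the test after the fact. A correlation with the actin ratio was not tested. At the same 5 times replicate 1 had a lower actin ratio than its group mean. The values were 2.41 against 2.56 at 2 h, 1.74 against 2.47 at 4 h and 1.38 against 1.76 at 12 h. They were 1.64 on the first array against 1.85 at 24 h, and 1.77 against 2.05 at 48 h. At 96 h replicate 1 was higher (2.55 against 1.8). The ubiquitin ratio went both ways. Whether RNA quality lies behind the shared deviation is therefore undecided.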

How the results depend on the processing

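The alternative without replicate 1 of any group was chosen only after the result was seen, and the other alternatives were planned. No named gene or list changed direction and kept a call, but the balance of rises and falls turned in some counts. For 12 h against 2 h, 2779 up and 2508 down became 2619 and 2650 with quantile normalization, 2464 and 2826 with median centring and 285 and 387 with a minimum change of 2-fold. For 96 h against 24 h, 630 and 593 became 477 and 535 with the filter at the 60th percentile, 955 and 1000 with array quality weights, 674 and 703 with the first 24 h replicate 1 array only and 743 and 805 without replicate 1 of any group. For 48 h against 24 h, 9 probe sets became 4 with a pseudocount of 1, 2 with the filter at the 60th percentile, 35 with array quality weights, 5 with the first 24 h replicate 1 array only, 2 with both as separate samples and 24 without replicate 1 of any group. For 96 h against 24 h array weights gave 1955. A minimum change of 2-fold left 46, 672, 136, 115 and 3822 of the probe sets for 4 h, 12 h and 24 h against 2 h, 96 h against 24 h and mature against developing leaves, by its construction. The 1 passing gene list test became 7 without a filter, adding sugar starvation at 12 h and 24 h against 2 h and in mature leaves and cell cycle in mature leaves (each 0.023) and photosystem at 12 h and stomatal development in mature leaves (each 0.045), and 0 by camera with an estimated correlation. With the filter at the 60th percentile 30 of the 48 tests could be run, of which 0 passed, and the flavonoid list was not among them because under 3 of its members were left. Except where construction shows it, the cause was not tested. The other planned counts, left-out replicates aside, lay within 1.5 times.

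Leaving out 1 replicate gave 283 to 372 probe sets for 4 h against 2 h, 4710 to 5191 for 12 h, 1325 to 1605 for 24 h, 0 to 17 for 48 h against 24 h, 733 (without 24 h replicate 3) to 1359 for 96 h against 24 h, 7496 to 8776 for mature against developing leaves, 7322 to 8074 over time and 0 to 1 list tests. With 1 mature array left, it is assumed to vary like the other groups. Among genes named for size, 13 calls were lost over other settings and 21 over left-out replicates, and among list members 45 and 86 were lost and 30 and 15 gained. Of 60 pairs of same-numbered replicates 28 correlated above 0.1, in a range of -0.09 to 0.62, and 14 of 24 replicates correlated best with their own number, a hint of some shared structure. Not all pairs did and the labels name no shared batch, so the comparisons and the splits left the numbers out. Array codes in the titles run in rounds by replicate number, with the mature arrays last. Whether they give an order of processing is not stated, and any such order could not be told apart from leaf age. With a replicate block the counts were 464, 5609, 1907, 11, 1474 and 8830, each higher than without it. PSAE-1 in mature leaves had adjusted p = 0.073 with it. Low signals near background limit the genes under 27.8.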

Other observations

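All tests of gene families in this part were chosen only after the result was seen.

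Autophagy genes were higher in mature than in developing leaves at 24 h. All 8 tested ATG genes passed over all probe sets, with a median log2 change of 1 (camera over 29 families and 174 tests, adjusted p = 0.0054, and adjusted p = 0.65 with an estimated correlation). ATG8F was higher by 2.45 ± 0.15 on the log2 scale, ATG8E by 2.1 ± 0.32 and ATG8H by 1.78 ± 0.19. ATG8 proteins are carried on the membranes of autophagosomes. At 12 h against 2 h, 5 of the 8 rose, among them ATG8E by 0.96 ± 0.26 and ATG8F by 0.72 ± 0.12, and the family did not pass (adjusted p = 0.082). At 24 h against 2 h none of the 8 rose by limma, where 3388 of all probe sets tested had an unadjusted p under 0.05. The 2 that fell were ATG8E with a log2 change of -1.01 ± 0.26 and ATG8H with -0.46 ± 0.15 (family median -0.2, adjusted p = 0.32). This comparison and that with mature leaves share the 24 h developing samples. ATG8E in developing leaves was lower at 24 h than at 2 h or 12 h. Its difference in mature leaves therefore depends on the time chosen. Genes of the plastid chromosome had a median log2 change of 0.25 at 24 h against 2 h over 68 genes (adjusted p = 0.0044, and adjusted p = 0.72 with an estimated correlation), of which 2 passed singly. In mature leaves 12 of them were higher and 13 lower, and the family did not pass (adjusted p = 0.38).

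The array assigned to no group correlated across probe sets at r = 0.986 with 4 h replicate 1 and 0.969 with 2 h replicate 1, where probe sets are not independent replicates. Pairs of 4 h replicates had r of 0.97 to 0.978. Its signal was 195 for GI, 57.7 for SPCH, 196 for AT4G32340 and 1780 for CCL. The arrays both titled 24 h replicate 1 differed by a root mean square of 0.286 on the log2 scale (r = 0.979), with 107 probe sets over 2-fold apart, and pairs of 24 h replicates differed by 0.257 to 0.377 when the first of these arrays stood for replicate 1. The second array differed from replicates 2 to 4 by 0.376 to 0.442.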
